A study of Mus musculus with 9 samples.

How the data were processed

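The series compared 3 subsets of splenic NK cells from B6.Rag-/- mice aged 7 to 10 weeks, with 3 arrays for each subset. Per the labels' protocols, total RNA was extracted with Trizol and column purification, checked on a Bioanalyzer, converted to biotin-labelled cRNA and hybridized. The arrays were Illumina mouse bead arrays, per the file headers and probe names. Groups, replicate numbers, sex and pool size were taken from the labels.

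The values analysed were the authors' deposited non-normalized intensity of each of 45281 probes on each array, a linear bead signal with neither background correction nor normalization. Per the file headers, each intensity came with a detection p-value. The authors also deposited a table of processed log2 values, whose columns share a median of 6.97. These log2 values matched quantile-normalized log2 intensities without background correction to within 5e-09, so they were used as an alternative that is identical to quantile normalization. The submitters' processing notes name limma without a version or a role. The scanner software and the settings behind the deposited values are not given in the sources used here. No column of per-sample values remained without a sample.

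Probes were named through a table of probes and genes for this series, with symbols updated by Entrez ID for 34807 probes. Of all probes 34885 had 1 gene symbol, 18 had several and 10378 had none, and no gene was named from a probe of the latter kinds. Signals were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3 (offset 16, with control probes inferred from the detection p-values). This offset compresses the folds of dim genes. Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept (17202, of which 14546 had 1 symbol), and each gene was represented by its probe with the highest mean, which left 9365 genes. Probes of Ly49 receptors, histones and other families of near-identical genes may report related genes, so their values are uncertain.

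All 9 arrays entered a limma fit with a mean for each subset (6 residual degrees of freedom and 2.62 prior degrees of freedom), followed by eBayes and Benjamini-Hochberg adjustment at 0.05. Every adjusted p without another name comes from this fit, differences are given in log2 units with the standard error of the fit, and n is 3 arrays per subset. Where the gene was undetected on every array of the dimmer subset, or a named gene was detected on only 1 of its 3 arrays, the fold is given as "at least", from the brighter mean over the mean of, on each array, the higher of the lowest detected signal and the gene's own, with the fit's adjusted p. Log2 differences are always those of the fit. Where 2 of 3 arrays of the dimmer subset detected a named gene the fold is also that of the fit, and it would be lower with the third array at its background level, by a factor that is larger against the CD27+ subset with its dim array. No fold is given where a gene was undetected in both subsets. A gene was named if it was among the 10 highest or 10 lowest differences past the threshold with all arrays of one subset above those of the other, if it was among the up to 4 largest called members of a fixed list, or if it was a sort marker or sex-linked check gene. Clone and model names were left out. A few further called list members and the genes distinguishing B220+ cells from both subsets are named because their counts are small.

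The 15 gene lists and 10 marker lists of other cell types were fixed with the design, the tests and most alternatives before the data were examined. They cover NK lineage identity, less mature and terminally mature NK cells, cytotoxic granules, cytokines, mitosis and S phase, activation, MHC class II, interferon response, Ly49 and CD94/NKG2 receptors, chemokine receptors, transcription factors, glycolysis, oxidative phosphorylation and immediate-early genes, and markers of B lineage, plasmacytoid and conventional dendritic cells, macrophages, neutrophils, erythroid cells, platelets, T lineage, stroma and mast cells. The 22 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 31 such calls over the 3 comparisons 11 held with an estimated correlation, and fry made 31 calls, of which 26 were among those of camera. Other divisions of the 9 arrays into 3 groups also gave calls with the preset correlation, up to 32, so its p-values overstate the evidence. Where genes undetected in a subset change the median of a called list, it is also given with these genes at their bounds. The number of members called over all genes and the number called when adjusted over the list alone are both given. Some lists share genes, such as Cma1, Cx3cr1, Xcl1 and Ltb.

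The held-out position projects each array onto the axis from the CD27+ to the CD27- mean over 200 genes, with genes and axis taken from the arrays of the other replicate numbers. Exact permutation tests over the arrays were two-sided. The labels give same-numbered arrays of the 3 subsets a common sex and pool size. In each of the 9 pairs of same-numbered arrays, deviations from the group means were positively correlated (0.141 to 0.334, all over 0.1), and each array correlated best with its own number, so the numbers were taken to pair the arrays. The fit with this number as a block is an alternative, given beside a result where it changes a call. Other alternatives were quantile normalization without background correction, a background offset of 1, scaling to a common median, other filters on dim probes, other ways to combine probes, only the 6 arrays compared, a random block, sex as a covariate, trended and robust eBayes, array weights, other thresholds, lists without the genes they share, and leaving out each array and each replicate number.

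The steps were tested on simulated data with known answers on 9365 genes. For B220+ against CD27+ cells 26% of genes changed 2-fold, 66% of those changed 4-fold and 86% of those changed 8-fold were called. For B220+ against CD27- cells the shares were 18%, 76% and 94%, and for CD27- against CD27+ cells 20%, 80% and 74%. Of genes changed 1.5-fold 8%, 0% and 0% were called in the same order. At most 2 unchanged genes were called. The simulated noise was independent between genes and arrays, without the correlation seen between same-numbered arrays. False calls under that correlation were therefore not measured. A simulated group made at position 0.3 was recovered at 0.341. The simulated CD27+ and CD27- groups, made at 0 and 1, were recovered at 0.0880 and 0.966, so held-out positions were drawn inward.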

Results

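Gene expression was measured in natural killer (NK) cells taken from the spleens of mice that lack the Rag recombinase, and therefore lack mature B and T cells. The cells had been divided into a B220+ subset, a CD27+ subset and a CD27- subset. B220 is an isoform of the phosphatase CD45 best known from B cells, and B220+ NK cells have also been described under the name interferon-producing killer dendritic cells. CD27 is a receptor of the tumor necrosis factor receptor family that is lost as NK cells mature. Each subset was represented by 3 arrays. According to the labels, replicate 1 of each subset came from 8 pooled spleens of female mice, and replicates 2 and 3 each came from 10 pooled spleens of male mice. The labels number these replicates but do not describe how the pools were made, so p-values measure the spread between these 9 arrays.

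Mean signal per array lay between 402 and 576 on 8 arrays and was 184 on CD27+ replicate 2. That array detected 26.1% of its probes, against 34.0% to 37.5% on the other arrays. After normalization its lowest correlation with another CD27+ array was 0.924, against a lowest value of 0.983 within the B220+ subset and 0.987 within the CD27- subset. The number of arrays limits the precision of every comparison.

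The labels were first set against sex-linked transcripts. Xist, which silences an X chromosome in female cells, had log2 signals from 9.93 to 10.16 on the 3 arrays labelled female and from 4.43 to 4.62 on the 6 labelled male. The Y-linked gene Eif2s3y showed the opposite arrangement, from 4.49 to 4.79 and from 9.16 to 9.63. Cd27 reached a mean log2 signal of 13.15 in CD27+ cells and 11.39 in CD27- cells, a difference of -1.77 ± 0.12 (SE, n = 3 arrays per group; limma adjusted p = 0.000157). In B220+ cells Cd27 stood at 12.86. It differed from the CD27+ level by -0.29 ± 0.12 without passing the test (adjusted p = 0.637) and exceeded the CD27- level by 1.48 ± 0.12 (adjusted p = 0.000909). Because CD27 defined the sort, its difference between the CD27 subsets is not a finding. The low side of its difference between B220+ and CD27- cells likewise reflects the sort. The Ptprc probe reports no particular isoform of CD45 and showed no called difference, with adjusted p from 0.388 to 0.872. The NK markers Klrb1c, Ncr1 and Il2rb, and the integrins Itgam and Itgax, likewise passed in none of the 3 comparisons.

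The first comparison asked which transcripts distinguish B220+ from CD27+ NK cells. Batf3, a transcription factor required for cross-presenting dendritic cells, was 6.23-fold higher in B220+ cells (log2 difference 2.64 ± 0.15, SE, n = 3 per group, adjusted p = 0.000243), or 4.93-fold with the CD27+ array that did not detect it put at its background level. Tmem176b, a membrane protein of intracellular vesicles, was 9.50-fold lower in B220+ cells (-3.25 ± 0.14, adjusted p = 5e-05). Tnfrsf25, the death receptor family member that binds TL1A, was 8.37-fold lower (-3.07 ± 0.29, adjusted p = 0.00347), and Socs2, an inhibitor of cytokine signaling, was 5.48-fold lower (-2.45 ± 0.15, adjusted p = 0.000323). Ckb, the brain-type creatine kinase, was 8.00-fold lower (-3.00 ± 0.28). Il7r, the alpha chain of the interleukin-7 receptor, was 3.31-fold lower (-1.73 ± 0.15, adjusted p = 0.00262). Klrb1b, an inhibitory receptor of the NKR-P1 family, was 3.46-fold lower (-1.79 ± 0.15, adjusted p = 0.00262).

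In total 35 of 9365 genes passed, 18 higher and 17 lower in B220+ cells, and 34 of them differed at least 2-fold in the fit. Some of the 34 have an "at least" fold under 2, such as Gins2. Among the higher genes were the mitotic kinesin Kif15 (at least 2.20-fold), the recombination helicase Rad54b (3.32-fold), the GINS subunit Gins2 (at least 1.79-fold) and Uhrf1 (2.65-fold), which maintains DNA methylation at replication forks. Also higher were the fractalkine receptor Cx3cr1 (5.01-fold), Parm1 (3.05-fold), the histone gene H2ac21 (2.84-fold), the stress-responsive gene Ndrg1 (2.79-fold) and Tnfrsf13b (2.78-fold), which encodes TACI, a receptor for B cell survival factors. The remaining named lower genes were Podnl1 (at least 4.35-fold), Tmem176a (at least 3.83-fold), Fam184b (4.14-fold), the homing receptor Gpr15 (3.79-fold) and Trgv4, a variable segment of the T cell receptor gamma chain. Trgv4 was undetected on all B220+ arrays and at least 4.08-fold lower there (adjusted p = 0.00442). The transcription factor Rora (-1.42 ± 0.15) and the chemokine Cxcl10 (-1.20 ± 0.18) were lower as well. With the replicate number as a block 18 genes passed, 4 higher and 14 lower, of which 16 were among the 35. Kif15, Rad54b, Gins2, Uhrf1, Cx3cr1, H2ac21, Ndrg1, Tnfrsf13b, Tmem176a, Gpr15 and Cxcl10 then had adjusted p between 0.0566 and 0.099. Batf3, Tmem176b, Tnfrsf25, Ckb, Socs2, Trgv4, Fam184b, Klrb1b and Il7r passed in each of the 9 fits that left out 1 array. The other 18 of the 27 named calls were lost in at least 1 of them, and most of these 18 in the majority of them. Klra17 held in only 1 of these fits, and Cd22, Cox6a2, Cxcl10, Gins2, H2ac21, Ndrg1, Tnfrsf13b and Uhrf1 in 2. Cx3cr1, Gpr15, Parm1, Rad54b and Vpreb1 held in 3. The count of 35 was 14, 10 and 12 without B220+ replicates 1, 2 and 3, and 16 and 19 without CD27- replicates 1 and 2. The share of higher genes depended on the scaling, with 16 higher and 25 lower after quantile normalization without background correction and 7 higher and 15 lower with a background offset of 1. Scaling to a common median left 0 calls in limma, with 144 genes at an unadjusted p under 0.05.

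Mitotic and S-phase genes were shifted upward as a group in B220+ relative to CD27+ cells. All 25 measured members had positive differences, with a median of 0.59, or 0.58 with genes undetected in a subset at their bounds (camera adjusted p = 1.2e-10, and adjusted p = 0.169 with an estimated correlation). None of them passed over all genes, and 10 passed higher when adjusted over the list alone. Genes of less mature, CD27-positive NK cells were shifted downward, with a median of -0.40 over 10 measured members (adjusted p = 7.91e-06, and adjusted p = 0.169 with an estimated correlation). Il7r alone fell over all genes, and 3 fell when adjusted over the list alone. Under scaling to a common median this list's median was 0.14, beside 0.35 for all genes, which places it at -0.21 relative to them, against -0.45 as reported, and the list no longer passed (adjusted p = 0.0512, with 2.3e-08 to 0.169 over all alternatives). Of the terminal maturation genes, Cx3cr1 rose and 9 did not pass (adjusted p = 0.246). Among 21 Ly49 and CD94/NKG2 receptor genes Klrb1b fell and Klra17 rose. Klra17, undetected on the CD27+ arrays, was at least 1.46-fold higher (adjusted p = 0.0473, and 0.068 with the block), and its probe may not separate related Ly49 genes. The list as a whole did not pass (adjusted p = 0.246). The 16 NK lineage identity genes included no called member (adjusted p = 0.194), and neither did the 13 cytotoxic granule and death ligand genes (0.545), the 11 MHC class II genes (0.448), the 24 interferon response genes (0.0736), the 14 glycolysis genes (0.0517), the 24 oxidative phosphorylation genes (0.728), the 13 activation and checkpoint genes (0.246) or the 21 immediate-early and stress genes (0.724). Cytokines and chemokines (0.246) and chemokine receptors and adhesion molecules (0.0517) did not pass as groups. For transcription factors of lymphocyte development the median was 0.10, while the mean of -0.02 and the test pointed downward (adjusted p = 0.798), and Rora alone fell.

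Markers of other cell types moved along this comparison too. Of 5 measured B lineage genes, Cd22, an inhibitory coreceptor of B cells that 1 CD27+ array detected, was at least 1.69-fold higher (adjusted p = 0.0241, and 0.0745 with the block). Vpreb1, part of the surrogate light chain of B cell precursors, was undetected on CD27+ arrays and at least 1.61-fold higher (adjusted p = 0.0234, and 0.0787 with the block). The list median was 0.83, or 0.69 at the bounds (adjusted p = 0.000402, and adjusted p = 0.212 with an estimated correlation), and 2 members rose when adjusted over the list alone. Among 9 plasmacytoid dendritic cell markers Cox6a2, a cytochrome c oxidase subunit of heart and muscle, rose 2.60-fold (adjusted p = 0.0473, and 0.0634 with the block), and the list did not pass (adjusted p = 0.327). The 4 conventional dendritic cell markers did not pass as a group (adjusted p = 0.114), although Batf3 belongs to them. All 8 neutrophil markers had negative differences, with a median of -0.93 (adjusted p = 1.25e-05, and adjusted p = 0.212 with an estimated correlation), and 1 fell when adjusted over the list alone. The 12 monocyte and macrophage markers had a median of -0.49 and no called member (adjusted p = 0.0269, and adjusted p = 0.506 with an estimated correlation). That call was lost without B220+ replicate 1 (median -0.16, adjusted p = 0.370) and without CD27+ replicate 3 (median -0.04, adjusted p = 0.583). The 5 erythroid (adjusted p = 0.246) and 6 T lineage markers (adjusted p = 0.715) did not pass.

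**Figure D1:**
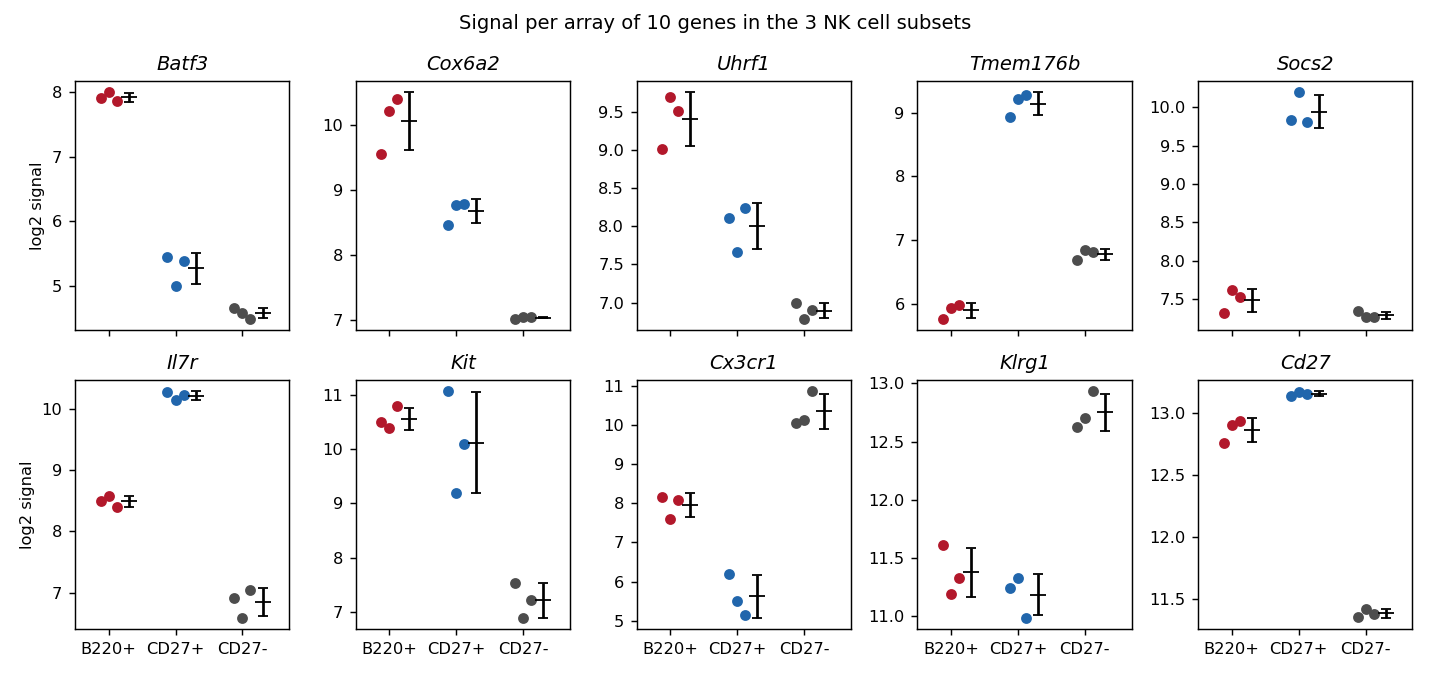
Normalized log2 signal of 10 genes on each of the 9 arrays, with replicates 1 to 3 from left to right within each subset and the mean with its SD (n = 3) drawn beside them. Batf3 averaged 7.92 in B220+ cells, 5.28 in CD27+ cells and 4.58 in CD27- cells, and Cx3cr1 averaged 7.95, 5.62 and 10.35 in the same order.

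The next comparison set B220+ against CD27- NK cells. H2-Oa, which modulates peptide loading of MHC class II, was 13.5-fold higher in B220+ cells (3.75 ± 0.30, SE, n = 3 per group, adjusted p = 0.000909), and Kit, the stem cell factor receptor, was 10.2-fold higher (3.35 ± 0.41, adjusted p = 0.00504). Ltb, which encodes lymphotoxin beta, was 8.73-fold higher (3.13 ± 0.22, adjusted p = 0.000674). Batf3 was undetected on the CD27- arrays and at least 6.78-fold higher in B220+ cells (adjusted p = 6.73e-05). In the other direction Kcnj8, a subunit of ATP-sensitive potassium channels, was at least 12.9-fold lower (-3.82 ± 0.42, adjusted p = 0.0031), and Cx3cr1 was 5.30-fold lower (-2.41 ± 0.32, adjusted p = 0.00673).

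Here 201 genes passed, 150 higher and 51 lower in B220+ cells, and 158 differed at least 2-fold in the fit. The other leading higher genes were the adhesion molecule Jaml (8.69-fold), Cd3d (8.28-fold), Cox6a2 (8.10-fold), the AP-1 component Fosb (7.36-fold), Emb, which encodes embigin (7.26-fold), and Ier5l (7.04-fold). The other leading lower genes were the endoplasmic reticulum peroxidase Gpx8 (5.43-fold), Nhsl2 (5.37-fold), the chromatin remodeling subunit Smarcd3 (4.56-fold), the platelet glycoprotein gene Gp1bb (4.17-fold), the neutrophil calcium-binding protein S100a8 (4.09-fold), Ly6c1 (3.82-fold), the chemokine Ccl9 (at least 3.43-fold) and the cadherin Cdh22 (3.18-fold), the last with adjusted p = 0.0445 and 0.0876 with the block. Of 49 named calls 31 held in each of the 9 fits without 1 array, among them H2-Oa, Kit, Ltb, Batf3, Kcnj8 and Cx3cr1. Nhsl2 and Gadd45b held in only 1 of these fits, S100a8, Plac8 and Cdh22 in 2, and Cd74, Egr1, Ier5l and Klra3 in 3. The count was 568 without CD27+ replicate 2, which is outside this pair but shares its estimate of the spread, and it was 122, 101 and 85 without B220+ replicates 1, 2 and 3 and 88, 90 and 99 without CD27- replicates 1, 2 and 3. Scaling to a common median left 0 calls in limma, with 225 genes at an unadjusted p under 0.05.

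Of 10 genes of less mature NK cells, 9 rose in B220+ relative to CD27- cells, and all 10 rose when adjusted over the list alone (median 1.64, camera adjusted p = 6.53e-25). The chemokine gene Xcl1 was among them (2.01 ± 0.17), with Kit, Ltb and Emb. Cd27, by which the CD27- cells were sorted, was another. Of 10 terminal maturation genes 6 fell, or 8 adjusted over the list alone (median -1.15, adjusted p = 2.95e-13). They included Klrg1, an inhibitory receptor of mature NK cells (-1.38 ± 0.17), the mast cell protease gene Cma1 (-1.65 ± 0.18), Ly6c1 (-1.94 ± 0.17) and Zeb2, a transcription factor of terminal maturation (-1.04 ± 0.19, adjusted p = 0.0324, and 0.0686 with the block). Of 25 mitotic and S-phase genes 7 rose, or 12 adjusted over the list alone (median 0.92, adjusted p = 7.7e-16). The survivin gene Birc5 rose 6.99-fold, thymidine kinase Tk1 5.67-fold, the transcription factor E2f1 5.30-fold and the spindle protein Nusap1 5.26-fold. Of 14 cytokine and chemokine genes 4 rose and Ccl9 fell, or 7 and 1 adjusted over the list alone (median 0.49, or 0.47 at the bounds, adjusted p = 3.03e-07), and Tnf, undetected in CD27- cells, was at least 2.78-fold higher (adjusted p = 0.00581). Of 13 activation and checkpoint genes Lag3 (1.80 ± 0.28), Cd83 (1.71 ± 0.21) and Cd69 (1.39 ± 0.21) rose, or 6 adjusted over the list alone (median 0.79, or 0.67 at the bounds, adjusted p = 3.81e-06). These lists also passed with an estimated correlation, at adjusted p = 0.00808, 0.0204, 0.0191, 0.0138 and 0.0179 in the order given.

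MHC class II and antigen presentation genes were higher in B220+ than in CD27- cells. All 11 measured members had positive differences (median 0.95, adjusted p = 1.07e-09, and adjusted p = 0.029 with an estimated correlation). H2-Oa and the invariant chain gene Cd74 (1.41 ± 0.28, adjusted p = 0.0427) rose over all genes, and 8 rose when adjusted over the list alone. H2-Ab1, a chain of the I-A molecule, differed by 0.95 ± 0.31 without passing (adjusted p = 0.229). Monocyte and macrophage markers moved the same way, with a median of 0.74 over 12 genes, or 0.68 at the bounds (adjusted p = 0.00228, and adjusted p = 0.225 with an estimated correlation), 0 called over all genes and 4 when adjusted over the list alone. The B lineage list had a median of 0.81 (adjusted p = 8.17e-05, and adjusted p = 0.0654 with an estimated correlation). Cd22, undetected on CD27- arrays, was at least 2.11-fold higher (adjusted p = 0.00828), and 4 B lineage genes rose when adjusted over the list alone.

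Immediate-early and stress genes were also higher as a group in B220+ than in CD27- cells (median 0.44, adjusted p = 8.17e-05, and adjusted p = 0.0631 with an estimated correlation). Fosb, Fos (1.51 ± 0.16), Egr1 (1.47 ± 0.26) and Gadd45b (0.86 ± 0.17, adjusted p = 0.0445, and 0.0618 with the block) rose, and 9 rose when adjusted over the list alone. The interferon response list passed at a median of 0.17, or 0.15 at the bounds (adjusted p = 0.00238, and adjusted p = 0.225 with an estimated correlation), with Usp18 called over all genes and 2 members over the list alone. NK lineage identity genes were slightly lower (median -0.22, adjusted p = 0.0136, and adjusted p = 0.0672 with an estimated correlation), with 0 called members and 1 lower when adjusted over the list alone. That call was lost under scaling to a common median (adjusted p = 0.167, at -0.10 relative to all genes against -0.20 as reported). It was also lost without genes shared by lists, where the median was 0.06 (adjusted p = 0.601, with 0.00271 to 0.601 over all alternatives). Granzyme genes Gzmm (1.95 ± 0.20) and Gzmk (1.32 ± 0.18) rose, while their list did not pass (adjusted p = 0.544). Cxcr3 (1.64 ± 0.15) and Ccr2 (0.91 ± 0.13) rose and S1pr5 (-0.93 ± 0.14) and Cx3cr1 fell among chemokine receptors, whose list did not pass (adjusted p = 0.119). Klra3, Klrb1b and Klrg1 fell among the Ly49 and CD94/NKG2 receptors (list adjusted p = 0.12). The lists of transcription factors (0.0765), glycolysis (0.0686) and oxidative phosphorylation (0.227) did not pass.

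Several marker lists of other cells differed between B220+ and CD27- cells. Neutrophil markers were lower (median -1.59, or -1.31 at the bounds, adjusted p = 7.42e-08, and adjusted p = 0.0654 with an estimated correlation), with S100a8 (-2.03 ± 0.40) and Lcn2 (-1.48 ± 0.20) called over all genes and 6 over the list alone. T lineage markers were higher (median 0.63, but 0.33 at the bounds, adjusted p = 0.00475, and adjusted p = 0.0975 with an estimated correlation). Cd3d (3.05 ± 0.28) and Cd3g (2.17 ± 0.38, adjusted p = 0.0237, and 0.0528 with the block), chains of the T cell receptor complex that NK cells also transcribe, were the 2 called members. The plasmacytoid dendritic cell list passed at a median of 0.12 (adjusted p = 0.0275, and adjusted p = 0.0975 with an estimated correlation), through Cox6a2 and Plac8 (2.00 ± 0.39). It was lost without B220+ replicate 3, where its median was -0.02 (adjusted p = 0.0567). The conventional dendritic cell list passed (median 0.69, or 0.51 at the bounds, adjusted p = 0.00219, and adjusted p = 0.161 with an estimated correlation) with Batf3 as its only called member among 4. Of 5 erythroid markers none passed, and the list median of -0.03 differed in sign from the mean of 0.12 and the test (adjusted p = 0.531). The platelet and stroma lists had 2 measured members each and the mast cell list 1, too few to test. Gp1bb (-2.06 ± 0.25) and Cma1 (-1.65 ± 0.18) fell in them, and Cma1 also stands in the terminal maturation list.

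**Figure D2:**
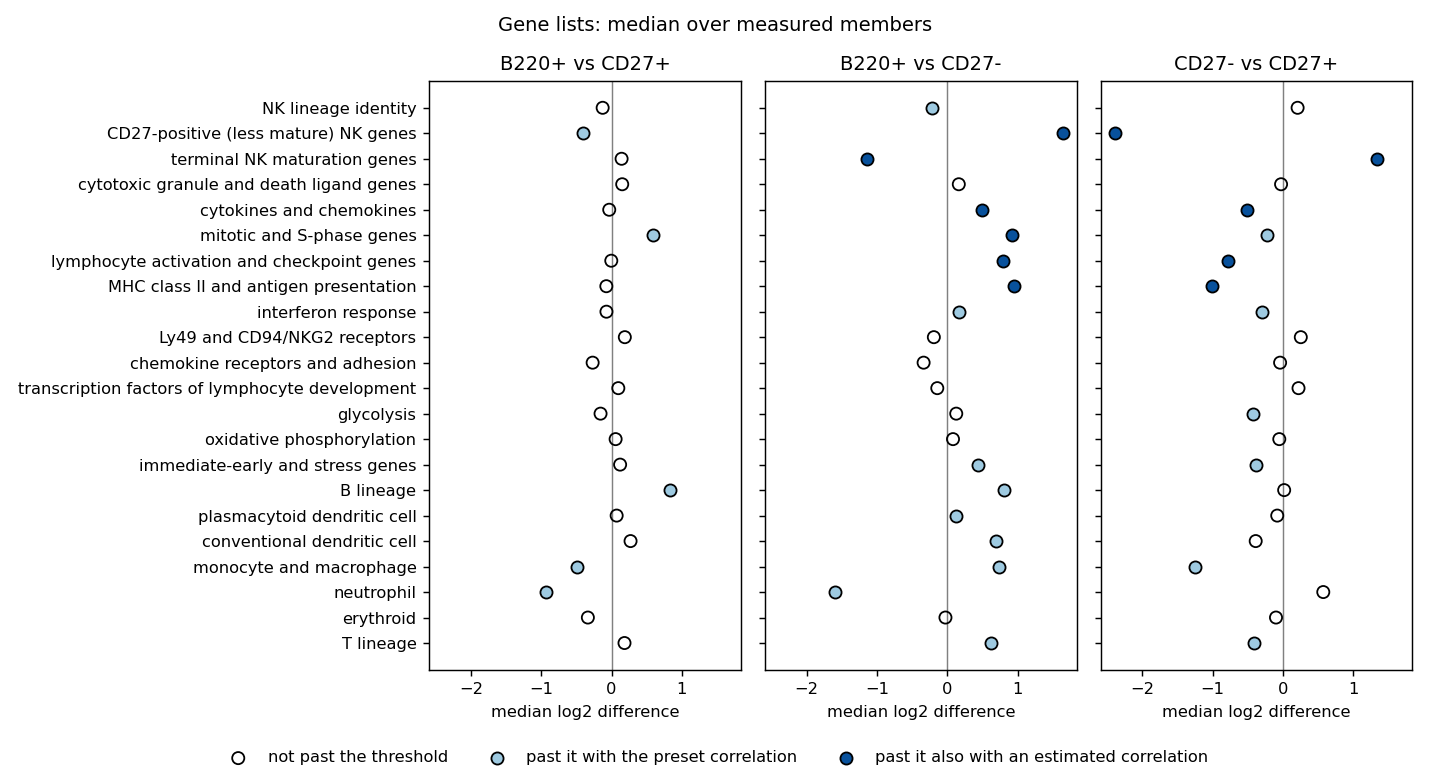
Median log2 difference over measured members (horizontal axis) of each of 22 gene lists (vertical axis) in the 3 comparisons, with open points for lists that did not pass camera, light points for those that passed with the preset correlation and dark points for those that also passed with an estimated correlation. Light or dark points number 5, 15 and 11 from left to right, and dark points 0, 6 and 5.

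The CD27 subsets were then compared with each other. Cx3cr1, the fractalkine receptor, was 26.6-fold higher in CD27- than in CD27+ cells (4.73 ± 0.32, SE, n = 3 per group, adjusted p = 0.000157). Gpx8 was 13.7-fold higher (3.77 ± 0.35, adjusted p = 0.000853) and Kcnj8 10.8-fold higher (3.44 ± 0.42, adjusted p = 0.00334). Ltb was 13.3-fold lower in CD27- cells (-3.73 ± 0.22, adjusted p = 0.000102), Il7r 10.3-fold lower (-3.37 ± 0.15, adjusted p = 5.56e-05) and Kit 7.50-fold lower (-2.91 ± 0.41, adjusted p = 0.00735).

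In this comparison 281 genes passed, 96 higher and 185 lower in CD27- cells, and 196 differed at least 2-fold in the fit. Parm1 (8.63-fold), Smarcd3 (at least 5.33-fold), Smpdl3b (6.86-fold), Denn2b (6.20-fold), the small GTPase Rac3 (5.32-fold) and Nhsl2 (4.97-fold) were also among the leading higher genes. The immunoglobulin-like receptor gene Lilr4b (12.1-fold), Jaml (9.77-fold), Emb (9.23-fold), the Notch pathway gene Dtx1 (8.00-fold), Asb2 (6.92-fold), the macrophage lectin ficolin A, Fcna (6.50-fold), and the oxysterol receptor Gpr183 (at least 5.47-fold) completed the lower genes. Of 64 named calls 39 held in each of the 9 fits without 1 array. Batf3, H2-DMa, Irf8, Klrb1f, Gapdh and Nhsl2 held in only 1 of these fits, and C1qc, Cd3g, Ctsc, Gzmk and Irf7 in 2. The count rose to 516 without CD27+ replicate 2, was 181 and 175 without B220+ replicates 1 and 3, 156 without CD27+ replicate 3, and 117, 119 and 117 without CD27- replicates 1, 2 and 3. The higher share moved with the scaling, to 217 higher and 258 lower after quantile normalization without background correction and to 5 higher and 0 lower after scaling to a common median, where 476 genes had an unadjusted p under 0.05 in limma.

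Of 10 genes of less mature NK cells 9 fell in CD27- cells, also when adjusted over the list alone (median -2.39, camera adjusted p = 3.57e-21), and of 10 terminal maturation genes 6 rose, also over the list alone (median 1.33, adjusted p = 2.41e-09). Cma1 (1.84 ± 0.18), Ly6c1 (1.79 ± 0.17), Klrg1 (1.57 ± 0.17) and Zeb2 (1.40 ± 0.19) were among the latter. Both lists were fixed from general knowledge of these subsets, and Cd27 is a member of the former. Of 14 cytokines and chemokines 5 fell and Ccl9 rose, or 6 and 1 adjusted over the list alone (median -0.51, adjusted p = 0.000146). Xcl1 fell 5.38-fold and Ifng by 0.69 on the log2 scale, Cxcl10 was at least 5.74-fold lower, and Tnf was at least 5.23-fold lower. Of 13 activation and checkpoint genes 5 fell, or 8 over the list alone (median -0.78, adjusted p = 1.91e-06), with Lag3 (-1.92 ± 0.28), Cd83 (-1.71 ± 0.21), Cd69 (-1.42 ± 0.21) and Icos (-1.34 ± 0.26) as examples. Of 11 MHC class II genes 4 fell, or 8 over the list alone (median -1.01, adjusted p = 1.7e-08), namely H2-Oa (-2.48 ± 0.30), Cd74 (-2.27 ± 0.28), H2-Ab1 (-1.77 ± 0.31) and H2-DMa (-0.70 ± 0.15). These 5 lists passed with an estimated correlation at adjusted p = 0.0126, 0.0461, 0.0346, 0.021 and 0.0461. Under scaling to a common median the median of all genes moved to 0.36, H2-DMa had a difference of 0.07, or -0.29 relative to that shift, and the cytokine list's median was 0.02, or -0.34 relative to it.

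Monocyte and macrophage markers were lower in CD27- than in CD27+ cells, alongside the MHC class II genes (median -1.25 over 12 genes, or -1.14 at the bounds, adjusted p = 8.68e-05, and adjusted p = 0.218 with an estimated correlation). The complement gene C1qc fell by 2.50 ± 0.50 on the log2 scale (adjusted p = 0.0359), a call that held in 2 of the 9 fits without 1 array. When adjusted over the list alone 7 markers fell. T lineage markers were lower as well (median -0.41, but -0.11 at the bounds, adjusted p = 0.0196, and adjusted p = 0.218 with an estimated correlation), through Cd3d (-2.58 ± 0.28) and Cd3g (-1.98 ± 0.38, adjusted p = 0.0306, and 0.0551 with the block), a call lost without CD27- replicate 3 (adjusted p = 0.0511). The 5 B lineage genes showed no called member, and their median of 0.02 differed in sign from the mean of -0.03 and the test (adjusted p = 0.82). Neutrophil (adjusted p = 0.0643, and 0.0477 with the block), plasmacytoid (0.112) and conventional dendritic cell (0.0627) and erythroid lists (0.233) did not pass. Cox6a2 (-1.64 ± 0.22) and the carbonic anhydrase gene Car2 (-1.63 ± 0.31) fell within them. Batf3, undetected in CD27- cells, was at least 1.09-fold lower there (adjusted p = 0.0498, and 0.0632 with the block), a difference that 8 of the 9 fits without 1 array did not call. Gp1bb rose (2.14 ± 0.25).

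The interferon response list was lower in CD27- cells (median -0.29, or -0.26 at the bounds, adjusted p = 0.000412, and adjusted p = 0.23 with an estimated correlation), with 5 of 24 genes called, or 6 over the list alone, among them Ifit3 (-1.78 ± 0.32), Usp18 (-1.43 ± 0.21), Irf7 (-0.85 ± 0.17) and Igtp (-0.79 ± 0.13). With scaling to a common median the list stood at 0.16 and Igtp at 0.02, or -0.21 and -0.34 relative to all genes. The immediate-early and stress list was lower (median -0.38, or -0.28 at the bounds, adjusted p = 0.00125, and adjusted p = 0.139 with an estimated correlation), with Fosb (-2.38 ± 0.35), Fos (-1.38 ± 0.16) and Gadd45b (-1.09 ± 0.17) called, or 5 over the list alone. The mitotic and S-phase list was lower (median -0.22, or -0.15 at the bounds, adjusted p = 0.00747, and adjusted p = 0.282 with an estimated correlation), with Tk1, E2f1 and the thymidylate synthase gene Tyms called, or 6 over the list alone. That call was lost without CD27+ replicate 3 (adjusted p = 0.152), and the median was 0.09 under scaling to a common median, or -0.27 relative to all genes. Glycolysis genes were lower (median -0.42, adjusted p = 0.00312, and adjusted p = 0.218 with an estimated correlation), with 1 of 14 called and 3 over the list alone. That gene, Gapdh, differed by -0.74 ± 0.15 (adjusted p = 0.0362, and 0.0501 with the block), and its sign turned to 0.07 under scaling to a common median, or -0.29 relative to all genes, while the glycolysis median became 0.30. Relative to all genes that is -0.06, against -0.48 as reported, and the glycolysis list no longer passed (adjusted p = 0.409, with 0.000537 to 0.409 over all alternatives). Klra3 (1.06 ± 0.15) rose and Klrb1f (-0.77 ± 0.16) fell among the Ly49 and CD94/NKG2 receptors (list adjusted p = 0.0586, and 0.0432 with the block), and Klrb1f stood at 0.04 under median scaling, or -0.32 relative to all genes. Gzmm fell (-1.78 ± 0.20), Gzmk fell (-0.95 ± 0.18, adjusted p = 0.0291, and 0.0501 with the block) and Ctsc, a protease that activates granzymes, rose (0.82 ± 0.15), in a granule list that did not pass (adjusted p = 0.724). S1pr5 (1.27 ± 0.14), a receptor for egress of NK cells, rose, and Cxcr3 (-2.28 ± 0.15) and Ccr2 (-1.04 ± 0.13) fell in the chemokine receptor list, whose median of -0.04 and mean of 0.08 differed in sign and whose test pointed downward without passing (adjusted p = 0.574). Zeb2 and Irf8 (0.72 ± 0.14) rose and Rora fell (-0.82 ± 0.15, adjusted p = 0.0273, and 0.0501 with the block) among transcription factors (list adjusted p = 0.469). NK lineage identity (0.454) and oxidative phosphorylation genes (0.491) did not pass.

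A further comparison asked which genes set B220+ cells apart from both CD27 subsets. Batf3, Cd22, Cox6a2, Gins2, Kif15, Ndrg1, Rad54b, Tnfrsf13b and Uhrf1 were higher in B220+ cells than in either subset, and Klrb1b and Tmem176b were lower than in either. Cox6a2, for example, averaged 10.05 ± 0.44 (SD, n = 3) in B220+ cells, 8.67 ± 0.18 in CD27+ cells and 7.03 ± 0.01 in CD27- cells. Tmem176b averaged 5.89 ± 0.11, 9.14 ± 0.18 and 6.77 ± 0.08. Independent lists of the same sizes would share 0.288 higher and 0.0926 lower genes, a value that leaves out the B220+ arrays common to both comparisons. Simulated unchanged groups shared 0 in each of 100 runs, but hardly any gene is called in such groups, so this gives no measure of what the common arrays add. Part of the 9 higher and 2 lower genes may come from those arrays. In a further 8 genes, Cx3cr1, Parm1, Rac3, Il7r, Cxcl10, Gpr183, Gstp3 and Serpina3f, B220+ cells lay between the subsets and differed from each. With the replicate number as a block 4 genes were called against both subsets, 2 higher and 2 lower. Of the 9 higher genes only Batf3 can be among them, since the others lost the threshold against CD27+ cells with the block. The count was 22 without CD27+ replicate 2, between 2 and 5 without B220+ replicates 1 to 3, 5 without CD27+ replicate 1, and 3, 3 and 4 without CD27- replicates 1 to 3. It was 13 higher and 1 lower after quantile normalization without background correction, 2 and 2 with an offset of 1, and 0 after scaling to a common median.

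The moderated F-test over all 3 subsets called 245 genes. It called 600 without CD27+ replicate 2, 142 and 131 without B220+ replicates 2 and 3, and 117, 112 and 121 without CD27- replicates 1, 2 and 3. Of the 281 genes that differed between the CD27 subsets, 120 also differed between B220+ and CD27- cells only, 12 between B220+ and CD27+ cells only, 12 in both and 137 in neither. The B220+ mean lay between the means of the CD27 subsets for 223 of the 281 (79.4%) and nearer to the CD27+ mean for 209 (74.4%). These shares use arrays that also selected the genes, so a position was computed on held-out arrays. On a scale where 0 is the CD27+ mean and 1 the CD27- mean, over 200 genes chosen from the arrays of the other replicate numbers, B220+ arrays lay at 0.358 ± 0.0863 (SD, n = 3), CD27+ arrays at 0.154 ± 0.0676 and CD27- arrays at 0.971 ± 0.0248. The B220+ arrays stood at 0.453, 0.336 and 0.285, above all CD27+ arrays and below all CD27- arrays. Simulated held-out positions were drawn inward, so 0.358 is to be read beside 0.154 and 0.971, not beside 0 and 1. The exact two-sided permutation p was 0.1 for each pair of subsets, the smallest that 3 arrays against 3 can give. This test exchanged arrays freely and left out their pairing by replicate number, which would allow fewer arrangements and a larger smallest p. It therefore cannot decide whether the positions differ.

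**Figure D3:**
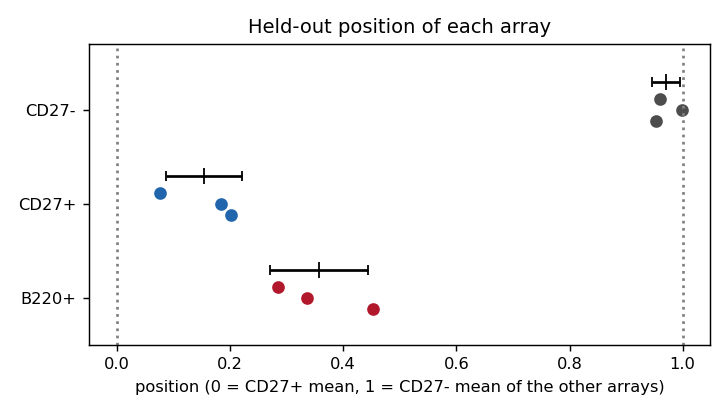
Held-out position of each array between the CD27+ mean (0) and the CD27- mean (1), with the group mean and SD (n = 3) drawn above the points of each subset. B220+ arrays range from 0.285 to 0.453, CD27+ arrays from 0.0765 to 0.202 and CD27- arrays from 0.954 to 0.999.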

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

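All tests in this paragraph were outside the original design and were chosen after the data were examined. Of the detected probes 2656 had no gene symbol or several, so no gene could be named from them. In the comparison of B220+ with CD27- cells 40 of these probes passed, 33 higher and 7 lower in B220+ cells. Between CD27- and CD27+ cells 22 passed, 5 higher and 17 lower in CD27- cells. Between B220+ and CD27+ cells limma called 0 of them, with 177 at an unadjusted p under 0.05. Which transcripts these probes measure was not analysed here.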

How the results depend on the processing

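The settings were planned, except for the position without CD27+ replicate 2, whose test was added after the result was seen. Counts are given in the order B220+ against CD27+, B220+ against CD27-, CD27- against CD27+, B220+ against both subsets, and the F-test, which were 35, 201, 281, 11 and 245 genes as reported. The cause of a moved count was not tested.

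Quantile normalization without background correction, and the deposited values identical to it, gave 475 genes between the CD27 subsets and 411 in the F-test. A background offset of 1 gave 22 genes for B220+ against CD27+ and 4 for B220+ against both. Scaling to a common median gave 0, 0, 5, 0 and 0 genes in limma, beside 144, 225 and 476 at an unadjusted p under 0.05 in the pairwise comparisons. It also moved the median of all genes to 0.35, -0.04 and 0.36, and between the CD27 subsets it turned H2-DMa to 0.0674, Igtp to 0.0230, Klrb1f to 0.0373 and Gapdh to 0.0673. Relative to that shift these were -0.29, -0.34, -0.32 and -0.29.

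Without a filter on dim probes 7 genes distinguished B220+ cells from both subsets. Only the 6 arrays compared gave 10, 534, 110 and 3 genes. The fixed replicate block gave 18 genes for B220+ against CD27+ and 4 against both, and the calls of named genes and lists that this pairing ended or added stand beside those genes and lists, and it ended no other named call. A random block gave 315 and 453 genes in the comparisons with CD27- cells, 19 against both and 380 in the F-test. Trended and robust eBayes gave 327, 487 and 422 in the latter comparisons and the F-test. Array weights gave 62, 754, 716, 25 and 802 genes, and an adjusted p under 0.01 gave 12, 85, 109, 2 and 106. Against the mean of both CD27 subsets 63 genes differed in B220+ cells. An estimated correlation left 11 of 31 list calls. The test fry kept 26 and did not call the monocyte and macrophage or neutrophil lists for B220+ against CD27+ (adjusted p = 0.440 and 0.132), the interferon or monocyte and macrophage lists for B220+ against CD27- (both 0.0890), or the mitotic list between the CD27 subsets (0.141). Of the called lists, monocyte and macrophage for B220+ against CD27+ was lost without a filter on dim probes (adjusted p = 0.0856) and with a stricter one (0.0815), and T lineage between the CD27 subsets without a filter (0.0742). Plasmacytoid dendritic cell for B220+ against CD27- was lost with the mean of the probes (0.0501, at a median of -0.01) and with every probe on its own (0.0638, at 0.09).

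Leaving out 1 array or 1 replicate number gave 0 to 51, 0 to 568, 0 to 516, 0 to 22 and 0 to 600 genes, and 26 to 35 list calls. For the position, CD27+ replicate 2 was the only array left out of the computation. Leaving out a replicate number only dropped its B220+ array from the mean, with genes and axis unchanged. The B220+ position was 0.310 to 0.394 over these settings, which does not test how far the axis depends on single arrays. The pairwise counts of 0 arose without replicate 3, where limma gave 402, 559 and 962 genes at an unadjusted p under 0.05 in the pairwise comparisons. Without replicate 1 they were 1, 5 and 24. Of 140 named calls 22, 114 and 0 held without replicates 1, 2 and 3, and 133, 113 and 116 with quantile normalization, an offset of 1 and the fixed block.

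Across all named calls and settings that leave nothing out, 1848 results were the same, 387 lost the threshold and 4 were reversed. Among leave-outs 1063 were the same and 617 lost it. For called lists 38 of the settings that leave nothing out and 12 leave-outs lost the threshold, and lists not called gained it in 48 and 25. Chip as a block was not run because no chip is given. A random block and robust eBayes were not run for the lists, nor a minimum of 2-fold for lists and the F-test, nor the F-test on 6 arrays. The position with axis genes chosen by adjusted p gave no value, since 1 of the left-out sets had 0 such genes.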

Other observations

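The tests below were chosen only after the result was seen, except for the test of type 1 innate lymphoid cell genes and the counts of other splits, of which those that hold each replicate number once per group among all 9 arrays were added afterwards.

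B220+ cells differed from CD27+ cells in 35 genes and from CD27- cells in 201. The dim CD27+ replicate 2 is argued against as the cause, since the ratio of these counts was 8.73 without replicate number 2 in any group and 5.74 with all arrays. The counts without that number, 30 and 262, come from the planned leave-out, so the ratio restates them and is no new test. B220+ cells lying nearer to CD27+ cells remains a candidate explanation, and the highest held-out position of a B220+ array was 0.453. That position comes from the same arrays and was known before the test was chosen. It describes the same pattern as the counts and gives no separate support. In each pairwise comparison 1 of 10 splits gave as many genes as the real 35, 201 and 281, the highest other split gave 0, and 10 splits are too few for a share under 0.05. The 3 other splits that part as many same-numbered pairs also gave 0 in limma. At an unadjusted p under 0.05 in limma the real splits had 711, 1158 and 1803 genes. All other splits had 182 to 721, 60 to 281 and 171 to 641 such genes. Between B220+ and CD27+ cells the highest other split, with 721, thus exceeded the real 711. The 3 splits that part as many pairs had 182, 236 and 405 there.

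MHC class II genes were higher in B220+ and CD27+ cells than in CD27- cells, alongside macrophage markers. Adjusting for the mean macrophage marker level changed the difference between B220+ and CD27- cells from 1.25 to 0.859 (95% interval 0.505 to 1.21), and that between CD27+ and CD27- cells to 0.646 (0.198 to 1.09). Noise in the markers weakens such an adjustment, so macrophages stay open as a source. B lineage cells could contribute too: Cd79b was 1.42 higher in B220+ than in CD27- cells (95% interval 0.528 to 2.31) and 0.58 higher in CD27+ cells (-0.31 to 1.47). Rag-deficient mice lack mature B cells, which does not speak against B cell precursors as a source. Expression by the NK cells themselves stays open and was not tested.

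Batf3, Cox6a2, Cd22 and 6 other genes were higher in B220+ cells than in both CD27 subsets. Plasmacytoid dendritic cells in the B220+ sort stay open, because their markers went both ways relative to the mean of the CD27 subsets. Siglech, a dim gene here, stood at -0.0521 (95% interval -0.34 to 0.24), Pacsin1 at -0.45 ± 0.22 (SE), Spib at -0.14 ± 0.21, Atp1b1 at -0.06 ± 0.11, Tcf4 at 0.25 ± 0.18, Lair1 at 0.26 ± 0.25 and Tlr7 at 0.35 ± 0.20, none of them called against either subset. Cox6a2, at 2.20, is among the genes that prompted the explanation. Plac8 was 2.00 ± 0.39 above CD27- cells (adjusted p = 0.0414) and 1.00 above CD27+ cells (adjusted p = 0.618). B lineage cells may contribute, since Cd79b lay 1.13 above that mean (95% interval 0.356 to 1.90), and so may a larger share of cycling cells, for which the mitotic list had adjusted p = 0.169 and 0.0191 with an estimated correlation. For genes lower in B220+ than in CD27+ cells, such as Tmem176b, Rora, Il7r and Gpr183, type 1 innate lymphoid cells in the CD27+ sort stay open. Of 10 listed genes 4 were measured, with a median of -0.13 (camera p = 0.586 with an estimated correlation).

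Among 100 splits of the 9 arrays into 3 groups, 3 gave as many genes differing from both other groups as the real 11 (highest other 86), 1 as many in the F-test as the real 245 (highest other 117), and 3 as many list calls as the real 31 (highest other 32). Most of these splits put same-numbered arrays together, so the 36 splits that hold each number once per group, as the real one does, were counted as well. Of them 1 reached the 245 of the F-test (highest other 86), a share under 0.05, and 2 reached 31 list calls (highest other 31), a share over 0.05. Splits with 0 genes in the F-test gave from 0 to 31 list calls, so calls with the preset correlation also arise without the real groups. Taking each group of these splits in turn as the one set apart, 6 of 108 choices reached 11 genes, also a share over 0.05. Chance is therefore not excluded for the lists. For the 11 genes this share cannot decide, since each of the 6 choices sets apart a whole real subset. Chance is not excluded for them either. For the F-test, 1 of 36 is the smallest share these splits can give, and 3 counts were set against them. That share argues against chance for the F-test without excluding it. Of the 6 choices 3 belong to the real split, with 11 for B220+, 21 for CD27+ and 131 for CD27- cells. The other 3, with 70 to 75, keep the 3 CD27- arrays together, which points to a structure of the samples. In the remaining splits 0 choices reached 11 genes, and the highest count was 6.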
